A study of Mus musculus with 8 samples.

How the data were processed

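The samples were mouse embryonic fibroblasts at E13.5, wild type or E2f3 null, immunoprecipitated with antibodies against E2F3, HELLS or H3K27me3 or with IgG. Per the labels' protocols, 100000000 cells and 10 µg of antibody were used, adapter-ligated DNA was amplified for 22 PCR cycles, fragments of 200 to 300 bp were cut from a gel, and 36 nucleotides were read from a single end on a Genome Analyzer IIx. Groups were taken from the genotype and antibody in the labels, which gave 1 library per group.

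The deposited read files give 1 aligned read per line on mm9, per the submitters' processing notes. The aligner and its mismatch settings are not given in the sources used here. Between about 98.3% and 98.9% of reads in each file were 25 bp long, shorter than the 36 nucleotides sequenced. Between 1640 and 4025 lines per file repeated a position and strand, so nearly all duplicates had been removed before deposit, and an interval from these reads does not treat PCR copies as separate molecules except where they escaped that step. Peaks were called by the authors per library with MACS 1.4.0beta against an IgG control named for the same genotype, with a p cutoff of 1e-05 and an effective genome of 1.87 Gb, per the file headers. The fragment size that MACS estimated ranged from 115 to 138 bp, per the file headers. For each peak the deposited tables give the count of tags, a score equal to 10 times the negative log10 of the p-value, the fold enrichment as a ratio of tags to the local expectation, and a false discovery rate in percent. The deposited summit files give the height of the tag signal at each summit, which was not scaled. The score in the peak table and in the peak interval file of each library was equal on every line. These scores were used only to rank, filter or describe peaks.

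The IgG files of both genotypes were compared and found identical, with 7223444 lines. The headers of the peak tables name separate controls of 3444066 tags for wild-type and 3791438 for E2f3-null cells, whose sum is 7235504. The deposited IgG reads were therefore used as 1 background library for both genotypes, which does not carry a genotype of its own.

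From the read files, 1 read per position and strand was kept and moved by 60 bp from its 5' end towards the fragment centre. Peaks of both genotypes that shared at least 1 bp were merged into regions for each antibody. Reads per region were counted and scaled by the distinct reads outside all 27092 peak regions of the series (21.5 Mb). A region was called lower or higher when the scaled ratio was at least 2-fold and its exact conditional binomial 95% interval excluded 1. For log2 ratios 0.5 was added to both counts. Shares carry exact Clopper-Pearson intervals. Peak overlap needed 1 bp, and 100 sets of peaks shuffled within chromosomes gave the share at random positions. The change at a class of regions was set beside 10000 random sets of regions matched on mean reads in 10 classes. For HELLS, sets were also drawn with replacement from the regions outside the class alone, and the interval of the difference came from resampling both sides 10000 times. The planned tests, alternatives and naming rules were chosen before the data were examined, except where the closing part says otherwise. The plan did not hold the joined H3K27me3 domains, the correlations across regions, the classes of score or the E2F3 change at H3K27me3 peaks. The alternatives were every deposited read, scaling by all distinct reads, scaling to the median of regions listed in both genotypes, a 1.5-fold threshold, peaks of score 100 or more, a 500 bp window at the summit, autosomes alone, overlap of at least 50% of the shorter peak, summits within 250 bp, and shuffling among 10 kb bins in the same of 5 classes of IgG count.

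The region test was tested on simulated counts for the real regions, with 200 regions changed by known folds per antibody. Among regions raised 4-fold it recovered 98.0% for E2F3, 96.0% for HELLS and 92.0% for H3K27me3, and among regions raised 2-fold 38.0%, 48.0% and 38.0%, since a 2-fold change sits on the threshold. Among regions lowered to 0.25 of their level it recovered 62.0%, 64.0% and 56.0%, and among regions lowered to 0.5 of their level 44.0%, 34.0% and 18.0%. It called 1.34%, 1.49% and 2.14% of unchanged regions. The simulation took the listed regions as given, scaled by all distinct reads and did not repeat peak calling. These shares therefore leave out false calls at regions listed because 1 library was high by chance. The criteria therefore missed many simulated changes, and recovery was not split by the number of reads in a region. The median H3K27me3 region held 16 wild-type and 7 E2f3-null reads.

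Named regions were the 5 peaks with the highest authors' score in each list and, for each antibody, the 5 regions with the largest fall and the 5 with the largest rise among those whose interval excluded 1, with ties taken in order of chromosome name. Regions on unplaced sequence or with more than 50 IgG reads per kb were left out. Coordinates are on mm9, counted from 1. An mm9 genome and gene annotation were not used here, so regions carry no gene names, and the planned results at promoters of 17 gene lists and for the E2F sequence motif at summits were not run. The gene table used for the chromosome of E2f3 is of assembly GRCm38.p6, and none of its coordinates were used. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.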

Results

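Chromatin immunoprecipitation followed by sequencing was carried out in mouse embryonic fibroblasts taken at E13.5, either wild type or lacking E2f3. E2F3 is a transcription factor of the E2F family, which controls genes of the cell cycle. HELLS is a helicase related to SNF2 that remodels chromatin, and H3K27me3 is the histone mark laid down by the Polycomb machinery and found on silent genes. Each genotype had 1 library for E2F3, 1 for HELLS, 1 for H3K27me3 and 1 for IgG, which gave 8 samples in 8 groups. There were no replicates, so each comparison below compares 2 libraries and not the conditions, and no p-value is given. Intervals are exact 95% intervals that cover counting error only.

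The 6 ChIP libraries held between 3799779 and 5640555 distinct reads. The wild-type E2F3, HELLS and H3K27me3 libraries held 4775822, 5318920 and 5640555 reads, and the E2f3-null libraries 4303093, 5377465 and 3799779. The IgG files of the 2 genotypes were identical, with 7219419 distinct reads, and were counted as 1 library. The authors listed 8889 E2F3 peaks in wild-type and 3314 in E2f3-null cells, 2489 and 4740 HELLS peaks, and 17064 and 7079 H3K27me3 peaks. Peaks of the same library took up 9.19% of the wild-type E2F3 reads (9.17 to 9.22) and 1.81% of the E2f3-null ones (1.80 to 1.82). For HELLS these shares were 1.14% (1.13 to 1.15) in wild-type and 2.96% (2.95 to 2.98) in E2f3-null cells. For H3K27me3 they were 14.3% (14.3 to 14.3) and 4.36% (4.34 to 4.38).

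The first comparison asked how far the E2F3 antibody signal depended on E2f3. Binding measured with this antibody fell across most of its regions in E2f3-null cells. Of 9643 regions listed in either genotype, 6439 (66.8%) were lower by 2-fold or more with an interval that excluded 1, and 92 (0.954%) were higher. The median log2 ratio of E2f3-null to wild-type reads over all regions was -1.45 (quartiles -2.04 and -0.92). The median log2 enrichment over IgG was 2.28 in wild-type and 0.89 in E2f3-null cells, so that part of the antibody signal over IgG remained without E2f3. Among the 25% of regions with the highest authors' scores 96.1% were lower, against 36.5% of the 25% with the lowest.

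Of the 8889 wild-type E2F3 peaks, 28.3% (27.3 to 29.2) overlapped an E2f3-null peak, against at most 0.315% in 100 shuffled sets. With peaks of score 100 or more in both lists this share was 9.42%. Of the 3314 peaks listed in E2f3-null cells, 75.9% (74.4 to 77.3) overlapped a wild-type peak. Regions listed in wild-type cells alone had a median log2 ratio of -1.71, and the 2467 regions listed in both genotypes had -1.16, with 1536 of them lower and 0 higher. The 799 regions listed in E2f3-null cells alone had a median of 0.25. The lists were called from the same reads, so regions in 1 list alone lean towards that library even without a change. Among 9443 E2F3 regions left unchanged in the simulation, which did not repeat peak calling, the same criteria called 53 higher. When libraries were scaled instead to the median of regions listed in both genotypes, 1459 regions were lower and 607 higher, which moved the lower share of calls from 98.6% to 70.6%, and the median log2 ratio to -0.29. This scaling removes any change common to those shared regions, so it cannot show a general loss of signal. With peaks of score 100 or more, 1 region was higher.

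**Figure D1:**
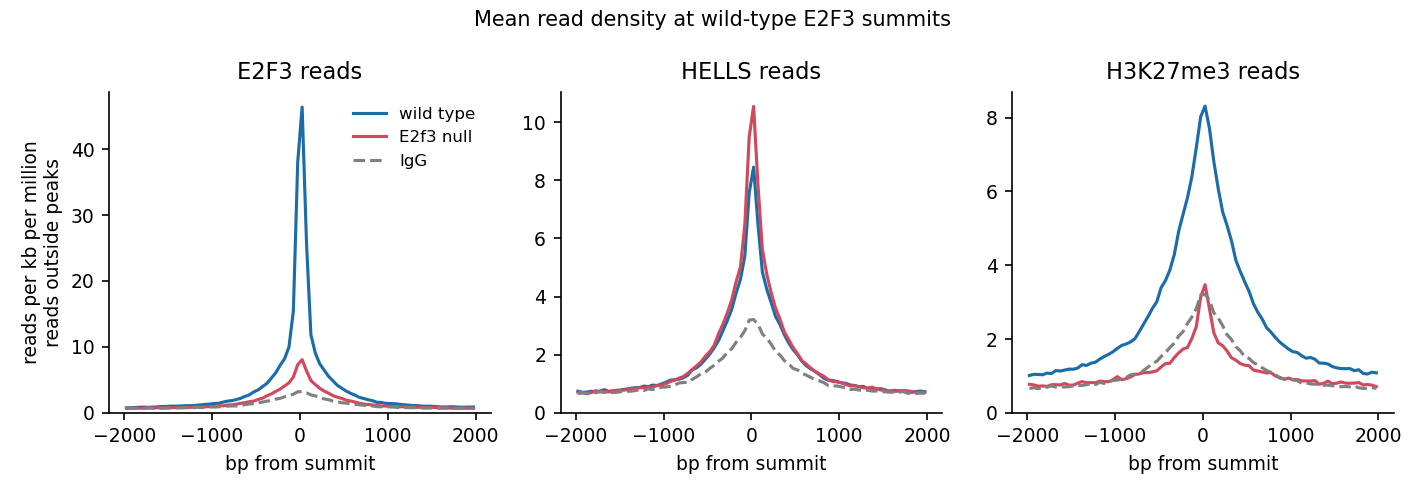
Mean density of distinct reads around the summits of the 8889 wild-type E2F3 peaks in 50 bp bins, in reads per kb per 1000000 reads outside peaks, for each antibody in wild-type cells (blue), E2f3-null cells (red) and the shared IgG library (dashed grey). In the bin beginning at the summit E2F3 density was 46.4 in wild-type and 8.07 in E2f3-null cells, HELLS density 8.46 and 10.5, and H3K27me3 density 8.31 and 3.47, and the vertical scales differ between panels.

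The E2F3 peak with the highest authors' score in wild-type cells lay on chromosome 4 from 82158835 to 82159411 (mm9). It held 220 wild-type reads and 13 E2f3-null reads, a scaled ratio of 0.0614 (0.0322 to 0.107), beside 13 IgG reads. The next ones lay on chromosome 5 from 66088491 to 66089792 (258 and 46 reads, ratio 0.185, 0.132 to 0.254) and on chromosome 8 from 81818544 to 81819330, in a region with 231 and 24 reads. A peak on chromosome 4 from 59561394 to 59562680 had 277 and 36 reads, and one on chromosome 10 from 90643936 to 90644919 lay in a region with 170 and 28. The largest fall was on chromosome 11 from 68821675 to 68822158, with 54 wild-type reads and 0 E2f3-null reads. With 0 reads set to a floor of 3 counts this was 17.3-fold lower, and the exact interval of the ratio ran from 0 to 0.0735. The next largest fall lay on the same chromosome from 94183211 to 94183563, with 41 and 0 reads. It was 13.2-fold lower at that floor, with an interval of the ratio from 0 to 0.0978.

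The strongest peaks of the E2F3 antibody in E2f3-null cells behaved differently from each other. The top one, on chromosome 6 from 83233863 to 83234050, lay in a region with 22 wild-type and 20 E2f3-null reads against 2 IgG reads, a ratio of 0.945 (0.489 to 1.81). The region around the peak on chromosome 3 from 144382557 to 144383490 had 139 and 38 reads, a ratio of 0.284 (0.193 to 0.409). The largest rise was on chromosome 14 from 96594140 to 96594310, with 0 wild-type and 10 E2f3-null reads. It was 3.46-fold higher at the floor of 3 counts, and the lower bound of its exact interval was 2.33. The other 4 regions chosen for a rise had 9 E2f3-null reads and 0 wild-type reads each.

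The deleted part of E2f3 itself was looked for as stretches with reads in wild-type and none in E2f3-null ChIP libraries. In the gene table of the assembly GRCm38.p6, E2f3 lies on chromosome 13. No stretch of at least 3 bins of 500 bp on that chromosome had 20 or more wild-type and 0 E2f3-null reads. Over the genome 3 such stretches were found, on chromosomes 1, 4 and 17, and 3 in the mirrored search for stretches empty in wild-type cells. The 3 wild-type ChIP libraries together held 5.42 background reads per kb, so 20 reads corresponded to about 3.69 kb on average. A deleted part that held fewer wild-type reads was not detectable at this depth. The genotype labels were therefore checked through the E2F3 antibody signal alone.

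HELLS binding was compared next, to see whether it depended on E2F3. Reads of the HELLS antibody showed no general loss at HELLS regions in the E2f3-null library. Over 5962 HELLS regions the median log2 ratio of E2f3-null to wild-type reads was 0.28 (quartiles -0.11 and 0.60), with 277 regions (4.65%) lower and 310 (5.20%) higher. Of the 277 lower regions, 276 were listed in wild-type cells alone. The balance depended on the threshold, with 288 lower and 638 higher at 1.5-fold, and 7 lower and 120 higher among regions from peaks of score 100 or more. The 1245 regions listed in both genotypes had a median log2 ratio of 0.18, with 0 lower and 12 higher. The 3484 regions listed in E2f3-null cells alone had a median of 0.48, and the 1233 listed in wild-type cells alone had -1.23. These opposite signs follow in part from sorting regions by lists called from the same reads.

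At the 6439 regions that lost E2F3 signal, HELLS reads were 1.16 times as many in the E2f3-null library (1.15 to 1.17), with a median log2 ratio of 0.17. At the 3204 E2F3 regions that were not lower, the HELLS ratio was also 1.16 (1.14 to 1.17). Across the 9643 E2F3 regions the log2 changes of HELLS and E2F3 had a Spearman correlation of 0.0479, where regions are not independent replicates. Across the 5962 HELLS regions this correlation was -0.111. HELLS enrichment over IgG at the regions that lost E2F3 signal had a median log2 of 0.77 in wild-type and 0.93 in E2f3-null cells. The E2F3 antibody in E2f3-null cells had 0.70 at the same regions. How much of the HELLS value was HELLS binding rather than enrichment shared by antibodies was not tested.

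The share of wild-type HELLS peaks that overlapped an E2f3-null HELLS peak was 50.5% (48.5 to 52.4), and the share of E2f3-null HELLS peaks that overlapped a wild-type one was 26.5% (25.2 to 27.8), or 9.10% with peaks of score 100 or more in both lists. The authors' false discovery rate was above 5% for 2196 of the 2489 wild-type HELLS peaks and for 0 of the 4740 E2f3-null ones. It was also above 5% for 1140 of the 3314 E2f3-null E2F3-antibody peaks and 4621 of the 7079 E2f3-null H3K27me3 peaks, and for 0 peaks of the wild-type E2F3 and H3K27me3 lists. Scaling to the median of regions listed in both genotypes gave 452 lower and 149 higher regions, which moved the lower share of calls from 47.2% to 75.2%. It takes out the common change of those shared regions, which had a median log2 ratio of 0.18. Of 5762 HELLS regions left unchanged in the simulation, which did not repeat peak calling, 38 were called lower and 48 higher.

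**Figure D2:**
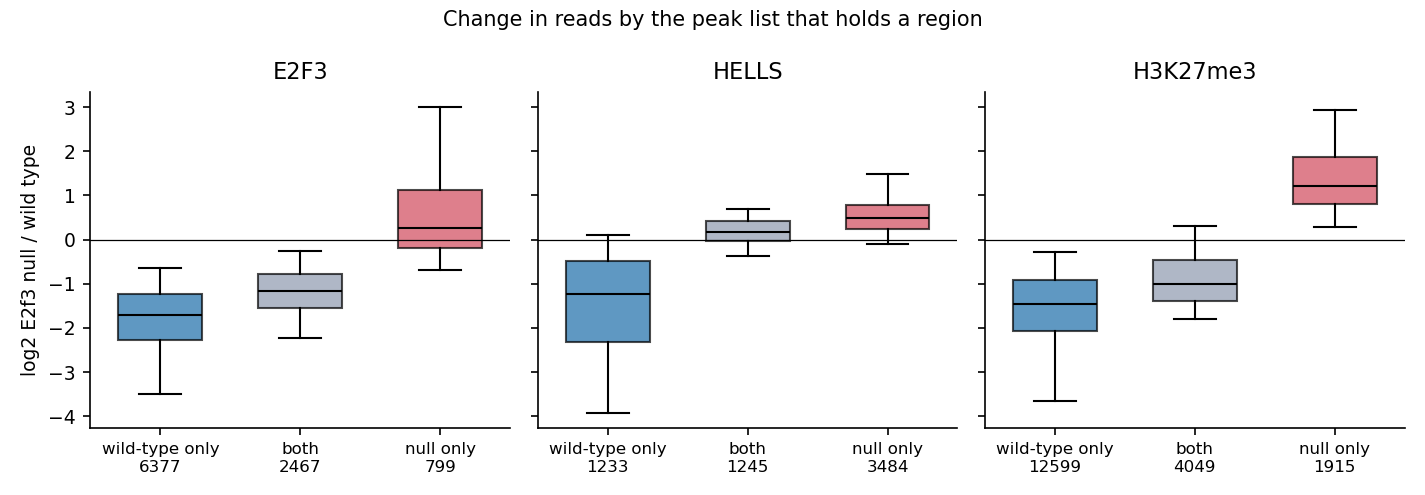
Distribution of the log2 ratio of E2f3-null to wild-type reads per region for E2F3, HELLS and H3K27me3, by whether the region was in the wild-type list, in both lists or in the E2f3-null list, with the number of regions under each box. Boxes span the quartiles with the median as a line and whiskers reach the 5th and 95th percentiles, and regions in both lists had medians of -1.16, 0.18 and -1.02 for the 3 antibodies. The lists were called from the same reads, so regions in 1 list alone lean towards that library.

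The HELLS region with the highest authors' score in both genotypes lay on chromosome 9 from 44688692 to 44689941 (mm9). It held 280 wild-type and 398 E2f3-null HELLS reads, a ratio of 1.41 (1.21 to 1.65), beside 33 IgG reads. E2F3 reads in this region were 84 in wild-type and 24 in E2f3-null cells. A region on chromosome 1 from 55144276 to 55145207 had 111 and 201 HELLS reads, a ratio of 1.80 (1.42 to 2.29), while its E2F3 reads were 129 and 22. On chromosome 17 from 28313800 to 28314777 HELLS reads were 82 and 215, a ratio of 2.60 (2.01 to 3.40), and E2F3 reads 95 and 24. The region on chromosome 5 from 66088572 to 66089762, which overlaps one of the strongest E2F3 peaks, had 65 and 83 HELLS reads, a ratio of 1.27 (0.906 to 1.78). The other 2 of the 5 highest-scoring wild-type HELLS peaks had ratios near 1. They lay on chromosome 15 from 79634205 to 79635522 (78 and 77 reads, ratio 0.980, 0.706 to 1.36) and on chromosome 10 from 44786558 to 44787437 (57 and 51 reads, ratio 0.889, 0.597 to 1.32).

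The largest HELLS changes rested on few reads. On chromosome 5 from 124626533 to 124626814 there were 12 wild-type and 0 E2f3-null reads. This was 4.03-fold lower at the floor of 3 counts, with an interval of the ratio from 0 to 0.357. On chromosome 12 from 77293938 to 77294350 there were 0 and 10 reads, 3.31-fold higher at that floor, with a lower bound of the interval of 2.23. These 2 regions held 5 and 2 IgG reads.

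The overlap of HELLS with E2F3 was measured in both genotypes. Most HELLS peaks lay on E2F3 peaks. Of the 2489 wild-type HELLS peaks, 65.8% (63.9 to 67.6) overlapped a wild-type E2F3 peak, and of 100 shuffled sets none passed 0.924%. Shuffling among bins of like IgG count raised the highest shuffled share to 2.33% and lowered the observed over mean shuffled ratio from 135 to 37.6. In the other direction, 18.5% (17.7 to 19.3) of wild-type E2F3 peaks overlapped a wild-type HELLS peak. Of the 4740 HELLS peaks in E2f3-null cells, 79.2% (78.0 to 80.4) overlapped a wild-type E2F3 peak and 51.2% (49.8 to 52.6) a peak of the E2F3 antibody in E2f3-null cells. Wild-type HELLS peaks overlapped that last list at 34.9% (33.0 to 36.8).

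Across the 9643 E2F3 regions, wild-type HELLS read density had a Spearman correlation of 0.460 with wild-type E2F3 density. It was 0.655 with the density of the E2F3 antibody in E2f3-null cells and 0.558 with IgG density. IgG reads themselves were 7.33 times as dense in E2F3 regions and 7.58 times as dense in HELLS regions as outside peaks. HELLS regions with a wild-type E2F3 peak (4185 regions) had a median log2 change of 0.32, and the 1777 without one had -0.0099. Sets drawn from the 1777 alone and matched on mean reads had a median of 0.33, and the difference from them was -0.015 (-0.029 to 0.0070). In the lowest 2 of the 10 classes of mean reads, which held 1012 of the 1777, the medians were -0.0099 with an E2F3 peak (181 regions) and -1.59 without. With peaks of score 100 or more in both lists, the difference between the classes turned from 0.33 to -0.085.

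H3K27me3 fell at many of its regions in E2f3-null cells. Of 18563 regions, 7669 (41.3%) were lower and 510 (2.75%) higher, with a median log2 ratio of -1.19 (quartiles -1.78 and -0.61). Among the 25% with the highest scores 75.1% were lower, with a median log2 ratio of -1.32. Among the 25% with the lowest scores 21.1% were lower, with a similar median of -1.05. The median log2 enrichment over IgG was 2.69 in wild-type and 1.72 in E2f3-null cells. Of the 17064 wild-type peaks 26.2% (25.5 to 26.8) were also listed in E2f3-null cells, and of the 7079 E2f3-null peaks 72.9% (71.9 to 74.0) were listed in wild-type cells.

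Under the scaling to the median of regions listed in both genotypes, 1047 H3K27me3 regions were lower and 2020 higher, which moved the lower share of calls from 93.8% to 34.1%. The median log2 ratio then was -0.18. This scaling removes any change common to the shared regions, so a general loss would not show under it. From peaks of score 100 or more there were 4805 lower and 53 higher regions, and with summits within 250 bp the shares of peaks listed in the other genotype were 17.3% and 41.8%. Of 18363 regions left unchanged in the simulation, which did not repeat peak calling, 191 were called lower and 202 higher.

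The strongest H3K27me3 peaks stayed enriched over IgG in both genotypes, and their ratios under the scaling by reads outside peaks were below 1. On chromosome 5 from 35620381 to 35624272 there were 568 wild-type and 164 E2f3-null reads beside 53 IgG reads, a ratio of 0.388 (0.324 to 0.462). On chromosome 6 from 52263131 to 52267758 there were 497 and 175, a ratio of 0.473 (0.396 to 0.563). The region on chromosome 2 from 146909293 to 146911817 stood among the 5 highest in both genotypes, with 517 and 219 reads, a ratio of 0.569 (0.483 to 0.668). The region on chromosome 1 from 91864206 to 91867461 had 324 and 195 reads, a ratio of 0.808 (0.673 to 0.968). Under the scaling to the median of shared regions the fall held on chromosome 5 (log2 ratio -0.35), but the intervals on chromosomes 6 and 2 no longer excluded 1 (-0.063 and 0.20). The fall on chromosome 1 then turned to a rise of 0.71, and the falls at 2 of the 5 highest E2f3-null peaks, on chromosome 4 from 124333331 and on chromosome 7 from 53087494, to rises of 0.21 and 0.28. The largest rise lay on chromosome 17 from 80329004 to 80329773, with 0 and 14 reads. It was 6.27-fold higher at the floor of 3 counts, and the lower bound of its exact interval was 4.45.

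The 5 largest falls in reads of the H3K27me3 libraries lay in 2 places. On chromosome X from 103381949 to 103382763 the wild-type library held 805 reads and the E2f3-null library 3, a ratio of 0.00500 (0.00103 to 0.0147). The wild-type E2F3 and HELLS libraries held 9 and 8 reads there, and IgG held 39. The other 4 of the 5 largest falls lay on chromosome 2 between 103572015 and 103588545, led by the region from 103574380 to 103574762 with 94 and 0 reads. That region was 23.3-fold lower at the floor of 3 counts, with an interval of the ratio from 0 to 0.0537. Whether the wild-type reads in these 2 places came from marked chromatin was not established, so the values compare reads and not the mark.

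H3K27me3 peaks joined across gaps of up to 5 kb formed 9429 domains in wild-type and 3746 in E2f3-null cells, of which 471 and 157 were longer than 10 kb. The longest wild-type domain covered 75.7 kb on chromosome 15 from 102739957 to 102815610. Its reads were 8.16 times the IgG level in wild-type and 5.06 times in E2f3-null cells, a ratio of 0.620 (0.578 to 0.666), and it held 0 wild-type E2F3 peaks. Domains on chromosome 2 from 74485980 to 74554766 and on chromosome 6 from 52153383 to 52216647 had ratios of 0.508 (0.473 to 0.546) and 0.527 (0.486 to 0.571), and held 6 and 5 wild-type E2F3 peaks. Of the 10 longest domains 5 held 0 such peaks, among them one on chromosome 19 from 44791098 to 44845386 with a ratio of 0.491 (0.451 to 0.534). In the 10 longest domains the ratio lay between 0.444 and 0.671. All these ratios rest on the scaling by reads outside peaks, where the E2f3-null to wild-type scale was 0.745. The scale from regions listed in both genotypes was 0.368, which raises every ratio and takes that of the longest domain above 1. The fall at the domains therefore depends on the scaling, and the scale from shared regions would hide a fall common to them.

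The remaining comparison set H3K27me3 beside E2F3 and HELLS binding. Of wild-type E2F3 peaks 20.6% (19.8 to 21.5) overlapped a wild-type H3K27me3 peak, against at most 1.25% of shuffled peaks, and of wild-type HELLS peaks 22.4% (20.8 to 24.1), against at most 1.45%. Shuffling among bins of like IgG count raised these maxima to 4.07% and 3.78%. The E2F3 share was 11.1% with peaks of score 100 or more and 12.6% with summits within 250 bp. In E2f3-null cells 16.3% (15.1 to 17.6) of E2F3-antibody peaks and 17.8% (16.8 to 18.97) of HELLS peaks overlapped an E2f3-null H3K27me3 peak. Regions of H3K27me3 with a wild-type E2F3 or HELLS peak (1923 regions) fell further, with a median log2 ratio of -1.48 against -1.16 at the 16640 others. This median stood at the percentile of 0 among 10000 random sets matched on mean reads, whose central 95% lay between -1.29 and -1.24. With peaks of score 100 or more in both lists the difference shrank from -0.32 to -0.077.

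Within 1 kb of the 8889 wild-type E2F3 summits the E2f3-null library held 0.378 times the wild-type H3K27me3 reads (0.375 to 0.381). This ratio was 0.407 (0.403 to 0.411) at the 1832 summits with a wild-type H3K27me3 peak and 0.330 (0.326 to 0.334) at the 7057 summits without one. At the latter the H3K27me3 reads were 1.08 times the IgG level in wild-type cells and 0.355 times in E2f3-null cells. Within 1 kb of the 2489 wild-type HELLS summits the ratio was 0.426 (0.420 to 0.431). E2F3 regions that carried a wild-type H3K27me3 peak (2118 regions) lost less E2F3 signal, with a median log2 ratio of -1.04 against -1.56 at the others. That median stood at the percentile of 100 among 10000 matched random sets, whose upper bound was -1.37. These sets were matched on mean reads and not on score. Of all E2F3 regions, 36.5% of the 25% with the lowest scores were lower, against 96.1% of the 25% with the highest. Whether weaker E2F3 peaks account for the smaller loss was not tested.

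Reads outside peaks were compared per chromosome. The X chromosome held more and the Y chromosome fewer of these reads in all 3 E2f3-null ChIP libraries. Relative to the autosomes, the E2f3-null to wild-type ratio on the X chromosome was 1.18 (1.17 to 1.19) for E2F3, 1.23 (1.22 to 1.24) for HELLS and 1.58 (1.57 to 1.59) for H3K27me3. On the Y chromosome the ratios were 0.469 (0.437 to 0.502), 0.496 (0.466 to 0.527) and 0.518 (0.477 to 0.562). The autosomes lay between 0.986 and 1.01 for E2F3, between 0.978 and 1.02 for HELLS and between 0.919 and 1.08 for H3K27me3. The X share of reads outside peaks in the single IgG library was 3.35% (3.34 to 3.36), between 3.10% and 3.64% in the wild-type and E2f3-null E2F3 libraries.

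**Figure D3:**
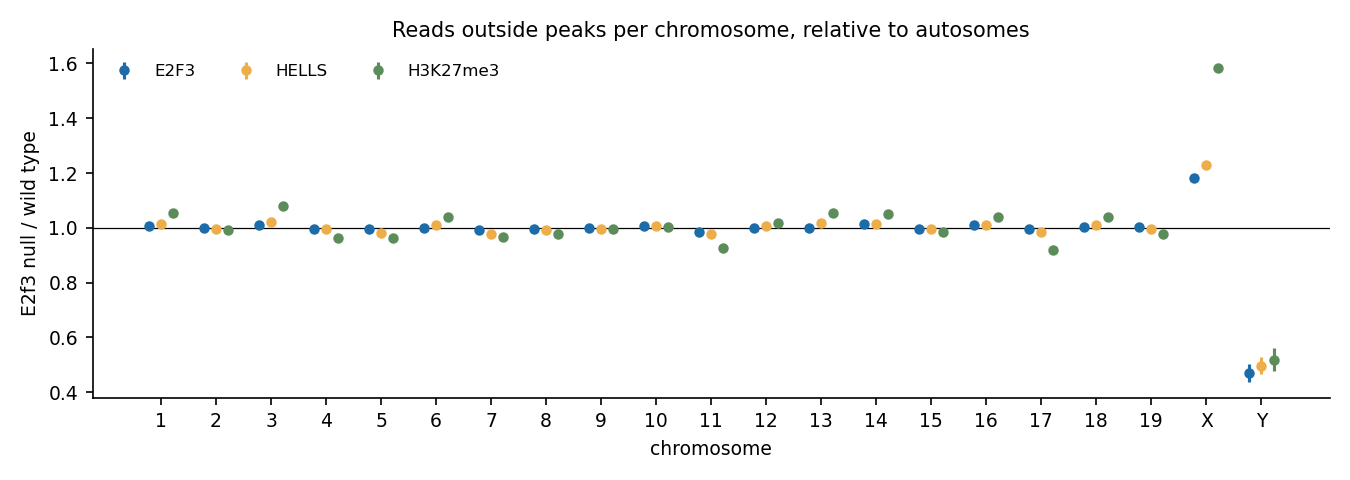
Ratio of E2f3-null to wild-type reads outside peaks for each chromosome, divided by the ratio over all autosomes, for the E2F3 (blue), HELLS (yellow) and H3K27me3 (green) libraries, with exact 95% intervals as bars, most of them smaller than the points. The X chromosome reached 1.58 for H3K27me3 against 1.18 and 1.23 for E2F3 and HELLS, and the Y chromosome lay between 0.469 and 0.518.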

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

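The tests on the X chromosome in this part were chosen after the result was seen. Reads outside peaks, which enter the comparisons of binding only as the scale of a library, differed between genotypes on the sex chromosomes. The ratio of E2f3-null to wild-type H3K27me3 reads on the X chromosome was 1.58, and that of HELLS reads on the Y chromosome was 0.496, both far outside the range of the autosomes.

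More H3K27me3 reads on the X chromosome were weighed against copy number, library quality and the sex of the cells. The X ratio of H3K27me3 was 1.29 times that of HELLS (1.28 to 1.30), which argues against X copy number alone, since that would move all antibodies equally. The highest autosomal H3K27me3 ratio was 1.08, on chromosome 3, which argues against weaker enrichment of the E2f3-null library as the whole cause. The highest Y ratio among the 3 antibodies was 0.518, with the X ratio above 1 in each, so a larger share of female cells in the E2f3-null cultures is consistent with the data, and the excess for H3K27me3 may then come from the inactive X, which carries this mark. An effect of E2f3 loss on the X chromosome was not tested apart from this, since the genotype and the makeup of the cultures coincide.

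The third result concerns the E2F3 antibody in cells without E2f3. Of its 3314 peaks there, 73.4% (71.9 to 74.9) also lay in the E2f3-null HELLS list, against at most 0.543% of peaks shuffled within chromosomes. Shuffling among bins of like IgG count was not run for this pair. IgG reads were 7.33 times as dense in E2F3 regions and 7.58 times as dense in HELLS regions as outside peaks. How much of the overlap came from sites prone to enrichment by any antibody was not tested.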

How the results depend on the processing

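The E2f3-null E2F3-antibody list and the matching of other regions on mean reads were added after seeing the data. Counting every deposited read and restricting to autosomes left the counts of lower and higher regions within 1.5 times, and autosomes alone left the shares within their intervals. Counting every read hardly tests anything, since few duplicates remained. Scaling by all reads also kept those counts within 1.5 times. A higher score leaves fewer peaks, and scaling to the median of regions in both lists removes any change common to those regions. The cause of the other moves below was not tested.

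Scaling to the median of regions in both lists gave 1459 lower and 607 higher E2F3 regions, 452 and 149 for HELLS, and 1047 and 2020 for H3K27me3. It also turned the fall at named H3K27me3 regions on chromosomes 4, 7 and 1 into log2 rises of 0.21, 0.28 and 0.71. A score of 100 or more left 1 higher E2F3 region, 7 lower and 120 higher HELLS regions, and 4805 lower and 53 higher H3K27me3 regions. A 1.5-fold threshold gave 638 higher HELLS regions.

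With a score of 100 or more, the share of wild-type peaks also listed in E2f3-null cells was 9.42% for E2F3, 56.2% for HELLS and 28.3% for H3K27me3, and the share of E2f3-null peaks also listed in wild-type cells was 9.10% for HELLS and 92.2% for H3K27me3. Overlaps between wild-type lists became 91.9% of HELLS with E2F3, 11.1% of E2F3 with H3K27me3 and 19.9% of HELLS with H3K27me3. With summits within 250 bp the shares of wild-type peaks were 20.2%, 41.6% and 17.3% and those of E2f3-null peaks 54.1%, 21.8% and 41.8% for E2F3, HELLS and H3K27me3, and the 3 overlaps 50.8%, 12.6% and 15.5%. Asking for 50% of the shorter peak moved H3K27me3 to 24.5% and 69.4%. Against the E2f3-null E2F3-antibody list, the HELLS overlap was 34.9%.

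Shuffling among bins of like IgG count lowered the observed over shuffled ratio from 135 to 37.6 for HELLS on E2F3, from 19.9 to 5.78 for E2F3 on H3K27me3 and from 21.7 to 7.51 for HELLS on H3K27me3. The HELLS difference between regions with and without E2F3 went from 0.33 to -0.085 with a score of 100 or more, to 0.36 in 500 bp windows and to -0.015 against matched others. The H3K27me3 difference went from -0.32 to -0.077 and -0.51. Among 57 named regions, 6 lost their interval in 500 bp windows, 1 when scaled by all reads, and 6 when scaled to shared regions, where 1 gained it. Promoter results for the gene lists and motif results, with all their alternatives, were not run.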

Other observations

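The tests of H3K27me3 reads at E2F3 summits without an H3K27me3 peak and at regions listed in E2f3-null HELLS alone, and of HELLS against other regions alone, were chosen after the results were seen, and the other tests in this part before. The wild-type H3K27me3 library held dense blocks of reads in 2 places. On chromosome 2 from 103561819 to 103598020 there were 20 H3K27me3 regions covering 9088 bp, and all 20 were lower in E2f3-null cells. Together they held 857 wild-type H3K27me3 reads, 8 in the E2f3-null H3K27me3 library, 31 in the wild-type E2F3 library, 31 in the wild-type HELLS library and 61 in IgG. On chromosome X, the middle 98% of the reads between 103381949 and 103382763 began and ended within 473 bp, from 103382067 to 103382539, with 450 on the plus and 412 on the minus strand when every deposited read was counted, repeats of a position included. IgG held 39 reads in that region.

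Outside peaks, bins of 1 Mb on the X chromosome were raised along its whole length. All 147 X bins had an H3K27me3 ratio above 1, with a median of 1.62, and all 147 did so for HELLS and for E2F3, with medians of 1.25 and 1.19. Single autosomal bins overlapped this range for H3K27me3, with 1542 of 2380 above 1, a median of 1.07 and a highest value of 1.51, against 1.14 to 2.14 on the X chromosome. For HELLS 1373 autosomal bins were above 1 and the highest reached 1.29, against a lowest X bin of 1.03. For E2F3 1282 were above 1 and the highest reached 1.21, against a lowest X bin of 1.03. The median log2 ratio of the 414 H3K27me3 regions on the X chromosome was -1.22 against -1.19 elsewhere, while 6.52% of them were called higher against 2.66% elsewhere. Over 2380 autosomal bins, which are not independent replicates, the ratios had Spearman correlations of 0.784 for H3K27me3 with HELLS, 0.542 for H3K27me3 with E2F3 and 0.482 for HELLS with E2F3.

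The HELLS list was longer in E2f3-null cells, with 4740 peaks against 2489. HELLS gain at sites that lost E2F3 signal stayed open, with a median log2 change of 0.33 there against 0.19 elsewhere. The percentile of 85.2 among matched random sets lay below the bound set beforehand. However, the sites made up 2999 of the 5962 regions from which these sets were drawn. Against matched sets of the other regions alone the percentile was 99, above that bound. The difference from those sets was 0.022, and its interval (-0.00049 to 0.049) included no change. For library scaling, the number of regions higher divided by the number lower was 1.12, although 120 were higher and 7 lower at a score of 100 or more. This balance came mostly from regions in 1 list alone, with 276 of the 277 lower and 298 of the 310 higher. Regions in both lists had 0 lower and 12 higher. The ratio therefore cannot decide on library scaling, which stayed open. So did general enrichment, since at the regions listed in E2f3-null HELLS alone the E2F3 antibody in E2f3-null cells exceeded IgG by a median of 1.97-fold, above the bound of 1.5-fold set beforehand, while E2f3-null H3K27me3, with a median of 0.460 times IgG but an upper quartile of 0.50 (log2), left open whether every antibody was enriched there. These levels are of E2f3-null libraries alone and do not measure a change between genotypes. In wild-type cells the medians there were 1.90-fold for HELLS, 4.30-fold for E2F3 and 1.47-fold for H3K27me3, and E2f3-null HELLS had 2.62-fold.

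H3K27me3 fell at 7669 of 18563 regions in E2f3-null cells. After scaling to the median of regions in both lists 16.5% of regions were 2-fold changed, between the bounds of 5% and 20% set beforehand. Of all regions 5.64% were then lower and 10.9% higher, so this share is not a remaining fall alone. The scaling also removes any loss common to the shared regions. Weaker enrichment of that library and a wider loss of the mark therefore cannot be told apart. A loss at regions with a wild-type E2F3 peak was consistent with the percentile of 0 among 10000 matched sets. However, the H3K27me3 ratio was 0.330 at E2F3 summits without an H3K27me3 peak, as low as at marked ones, so the further fall may reflect fewer reads over E2F3 sites in the E2f3-null library whether or not they carry the mark. An input library without antibody would bear on this and was not analysed here.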
